A study of Homo sapiens with 12 samples.

How the data were processed

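Gene expression was measured on 12 two-colour Agilent oligonucleotide arrays in HBL1 and TMD8, established human cell lines from diffuse large B-cell lymphoma of the activated type. Per the labels, total RNA was taken from cells in RPMI medium with 10% fetal bovine serum, and every array set the RNA of inhibitor-treated cells, labelled with Cy5 (red), against the RNA of DMSO-treated cells of the same line and time, labelled with Cy3 (green). The 3 groups were 15e, a PI3K inhibitor, in HBL1 at 12, 24, 36 and 48 h, 15e in TMD8 at the same times, and MLN120b, an inhibitor of IKKβ, in HBL1 at 6, 12, 24 and 48 h, with 4 arrays per group and 1 array per time. Inhibitor doses were not given in the sources used here. The labels did not state that the cultures of a group were separate, so p-values measure only the spread between these samples, which may be technical, and the response over time is part of that spread. No dyes were swapped, so a gene's dye effect is in each group mean and cancels in differences and slopes only if equal on all arrays.

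The spot intensities were mean foreground and median background intensities on a linear scale, made by the authors with Agilent Feature Extraction 10.5.1.1, per the file headers and the submitters' processing notes. The scanner's own log ratio of red over green was deposited on a log10 scale, after background subtraction and dye normalization per the file headers. The series value table was deposited by the authors without a stated unit, and each of its columns equalled the scanner's log10 ratio turned to log2, with a largest difference of 4.9e-08, so its scale and direction were settled, its column medians lay between 0.00 and 0.05, and it carried no further centring. That deposited log2 table left 21248 to 29287 of its 43376 listed spots with a value per array. The spot flags (outlying, saturated, well above background) were used as deposited.

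Background was corrected with normexp at an offset of 50 on all spots, and each array was normalized with loess, in which control spots and outlying spots had a weight of 0. Outlying spots, 107 to 193 per array, were then left out, no spot was saturated (0 on each array), and spots of 1 probe were averaged. The array held 45015 spots, of which 43376 were gene spots and 1639 controls, with 41000 different gene probes. A probe was tested where it was well above background in either channel on at least 4 of the 12 arrays, which kept 28365 probes. A gene was represented by its brightest probe (highest mean intensity over the 12 arrays), which gave 20562 genes and unnamed transcripts, 14234 of them with a current symbol and 5522 with more than 1 tested probe. Gene names came from the RefSeq table of GRCh38.p14, used for names alone: 26595 probes matched by accession, 2241 by the symbol in the files, 556 by an older symbol, and 11608 kept the files' name. Coordinates are those of the TMD8 files, which refer to hg19, 1-based, while the HBL1 files refer to hg18.

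Group means were tested against 0 and against each other with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per group over the 12 arrays, which share 1 estimate of the spread, and with Benjamini-Hochberg adjustment over the 20562 genes at 0.05. The inhibitors were compared on the 6 HBL1 arrays of the times they shared (12, 24 and 48 h). Time trends were slopes per doubling of the hours, fitted per group in 1 model. The tables were read with data.table (version 1.17.8) and jsonlite 2.0.0, and statmod 1.5.0 served the slide block. The 25 gene lists were fixed with all tests, groups and naming rules before the data were examined: NF-kB targets, STAT3 and cytokine signalling, interferon response, FOXO targets, MYC and ribosome biogenesis, cell proliferation, replication histones, cholesterol and fatty acid synthesis, ATF4 targets and amino acid metabolism, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, B cell identity, germinal centre B cell, plasma cell differentiation, antigen presentation by MHC class II, immediate early and BCR feedback genes, BCL2 family and caspase inhibitors, p53 targets, heat shock and proteotoxic stress, PI3K-AKT-mTOR components, NF-kB pathway components, and markers of T and NK cells, of myeloid cells, and of erythroid, stromal and epithelial cells. Each list was tested against all other genes with limma's camera (preset correlation 0.01), adjusted over the lists of a comparison. Camera with an estimated correlation between genes and limma's fry were alternatives.

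The named genes were 18 chosen in advance, the 8 highest and 8 lowest called means per group with the same sign on all 4 arrays and a current symbol, the 6 highest and lowest called differences whose arrays did not overlap, the 4 highest and lowest called slopes, and up to 4 members of each list with the largest changes, some of which are not reported here. Values are mean log2 ratios ± SD over arrays, n = 4 unless stated, and "adjusted p" is limma's. A list is said to rise or fall where camera called it, and a gene where limma called it. Where 1 channel was not well above background on any array of a group, a bound is given if the channels' normalized values allowed it, open to dye bias. Where both channels were, or no bound followed, the gene is said not to be above background and no change is read.

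Of probes, 56.7% to 70.5% were well above background in either channel. In green they were 43.7% to 46.9% (MLN120b) and 52.8% to 65.8% (15e). The number of arrays limits precision. Simulated data of 20562 genes, 200 changed in each comparison, gave no wrong sign (0). Of log2 changes of 0.5 and 1, 61.2% and 95.5% were recovered for 15e in HBL1 and 53.7% and 97.0% in TMD8. For MLN120b 59.7% and 95.5% were, between lines 29.9% and 83.6%, and between inhibitors 5.97% and 59.7%. For trends, in the same group order, it was 17.9% and 76.1%, 23.9% and 77.6%, and 68.7% and 91.0%. The real means and differences called 1032 to 10125 genes, a looser cut, so their shares do not describe recovery there.

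The alternatives were the scanner's log ratio, the deposited table, no background correction, an offset of 10, median centring in place of loess, no filter and a strict filter (both channels on all 12 arrays), the mean over a gene's probes, eBayes with trend and robust settings, the arrays of the groups compared alone, slide or time as a block, a slope in the design, a minimum mean of 0.5, hours on a linear scale, and leaving out each array in turn. A fit without the MLN120b array at 24 h was added after the data were seen. Each 15e group sat on a slide of its own, and MLN120b at 6 h and at 12, 24 and 48 h on separate slides, so slide and scan cannot be told apart from line and inhibitor.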

Results

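Gene expression was compared between inhibitor-treated and DMSO-treated lymphoma cells on 12 two-colour arrays, 4 for 15e in HBL1, 4 for 15e in TMD8 and 4 for MLN120b in HBL1. HBL1 and TMD8 come from diffuse large B-cell lymphoma of the activated type, in which NF-kB is active. 15e inhibits PI3K, the lipid kinase upstream of AKT, and MLN120b inhibits IKKβ, the kinase that releases NF-kB from its inhibitor IκBα. The ratios of each array were centred, so every change is relative to the middle of all genes on the same array. RNA added as spike-in controls lay above the median gene by 1.21 ± 0.64 on the TMD8 arrays, against -0.16 ± 0.26 and 0.07 ± 0.24 in the other 2 groups (n = 4 each). Median centring in place of loess shifted the median of all genes by 0.33 for 15e in HBL1, 0.20 for 15e in TMD8 and 0.66 for MLN120b, and values with median centring are given relative to this shift, for lists moved by over 1.5 times and called genes brought closer to 0 by as much. None of the list calls (0) was kept when camera estimated the correlation between genes, and that adjusted p stands beside each call.

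15e in HBL1 was measured to learn which genes follow PI3K in this line. SH2D5 had the lowest mean log2 ratio, -3.02 ± 0.12 (n = 4, adjusted p = 5.44e-07). EGR1, a transcription factor induced within minutes of B-cell receptor signalling, fell by 2.42 ± 0.02. BATF3 (-2.77 ± 0.70), RNF183 (-2.54 ± 0.72), ASS1 (-2.47 ± 0.92), UCHL1 (-2.36 ± 0.62), LRRC20 (-2.32 ± 0.72) and MCM4 (-2.26 ± 0.81) fell as well. LTB, which encodes lymphotoxin beta, rose most, by 3.40 ± 0.76 (adjusted p = 5.78e-05). It was followed by CTSF (3.37 ± 0.71), STRA8 (3.31 ± 0.95), NLRP7 (2.92 ± 0.32), TXNIP (2.71 ± 0.27), SUSD3 (2.69 ± 0.73), CEACAM1 (2.55 ± 0.76) and PINK1 (2.54 ± 0.52). Limma called 10125 of 20562 genes, 5305 higher and 4820 lower (52.4% higher), and 1210 had a mean of at least 1 in size.

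Genes of cell growth and division fell in HBL1 under 15e. Of 43 proliferation genes, 37 fell and 6 were not called, and 42 fell when adjusted over the list alone. Their median was -1.34 (adjusted p = 2.31e-12, and adjusted p = 0.435 with an estimated correlation). The replication factor gene MCM10 had a mean of -2.18 ± 1.06 and thymidine kinase TK1 of -2.12 ± 1.07. Of 35 genes of MYC and ribosome biogenesis, 31 fell and 4 were not called, and 32 fell when adjusted over the list alone. The list had a median of -0.72 (-0.31 with median centring, adjusted p = 3.49e-12, and adjusted p = 0.419 with an estimated correlation). The nucleolar gene NOLC1 fell by 1.79 ± 0.51 and the polyamine enzyme ODC1 by 1.70 ± 0.28. MYC fell by 0.67 ± 0.20, although its probes ranged from -0.67 to 0.05. CCND2, which encodes cyclin D2, fell by 1.77 ± 0.48. With median centring MYC was at -0.14, ODC1 at -0.96 and TK1 at -1.23.

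Metabolic lists were lower in HBL1 under 15e. Among 35 ATF4 targets and genes of amino acid metabolism, 28 fell and 7 were not called, the same when adjusted over the list alone (median -1.01, adjusted p = 1.27e-10, and adjusted p = 0.419 with an estimated correlation). ATF3 (-2.10 ± 0.68), the serine synthesis enzyme PHGDH (-2.06 ± 0.42) and the glutamine transporter SLC1A5 (-1.84 ± 0.53) were among them. Of 30 glycolysis and hypoxia genes, 17 fell, 3 rose and 10 were not called, the same when adjusted over the list alone (median -0.64, adjusted p = 0.000142, and adjusted p = 0.445 with an estimated correlation). PFKFB4 (-1.78 ± 0.56), ENO1 (-1.75 ± 0.37) and LDHA (-1.58 ± 0.60) fell. Of 31 cholesterol and fatty acid genes, 19 fell, 1 rose and 11 were not called, and 20 fell when adjusted over the list alone (median -0.48, adjusted p = 4.11e-05, and adjusted p = 0.445 with an estimated correlation). ACAT2 (-1.17 ± 0.35) and DHCR7 (-1.17 ± 0.41) had its lowest means. Of 33 oxidative phosphorylation genes, 22 fell, 3 rose and 8 were not called, the same when adjusted over the list alone (median -0.38, 0.18 and so opposite in sign with median centring, adjusted p = 3.42e-05, and adjusted p = 0.419 with an estimated correlation). ATP5MC1 (-1.13 ± 0.10) and NDUFB8 (-0.80 ± 0.07) fell. Of 18 heat shock genes, 13 fell, 1 rose and 4 were not called, and 13 fell and 2 rose when adjusted over the list alone (median -0.74, adjusted p = 0.000121, and adjusted p = 0.419 with an estimated correlation). The chaperone genes HSPE1 (-1.33 ± 0.35), HSPB1 (-1.31 ± 0.28) and HSP90AA1 (-1.20 ± 0.16) were among them. Median centring ended the calls of cholesterol (median -0.14, adjusted p = 0.161), oxidative phosphorylation (0.376) and heat shock genes (-0.18, 0.232), and left glycolysis at -0.38. Genes moved were ENO1 (-1.0), LDHA (-0.87), ACAT2 (-0.64), DHCR7 (-0.58), ATP5MC1 (-0.72), NDUFB8 (-0.14), HSPE1 (-0.43) and HSP90AA1 (-0.74).

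Other lists rose in HBL1 under 15e. Of 28 FOXO targets, genes linked to factors that AKT restrains, 19 rose, 3 fell and 6 were not called. Adjusted over the list alone, 19 rose and 4 fell. The median was 0.69 (adjusted p = 0.000134, and adjusted p = 0.419 with an estimated correlation). TXNIP, TSC22D3 (1.41 ± 0.15), PIK3IP1 (1.01 ± 0.13) and BCL6 (1.18 ± 0.54), a transcriptional repressor found in germinal centre B cells, rose. The 3 that fell were the cyclin gene CCND2, CDKN1A (-1.54 ± 0.50) and KLF2 (-0.51 ± 0.22). Of 41 cytosolic ribosomal protein genes, 31 rose and 10 were not called, and 33 rose when adjusted over the list alone (median 0.46, adjusted p = 3.47e-10, and adjusted p = 0.419 with an estimated correlation). RPS20 (0.89 ± 0.07) was among them. Of 35 B cell identity genes, 19 rose, 7 fell and 9 were not called, and 22 rose when adjusted over the list alone (median 0.39, adjusted p = 0.0314, and adjusted p = 0.445 with an estimated correlation). VPREB3 (2.32 ± 0.35) and the BAFF receptor gene TNFRSF13C (1.55 ± 0.51) rose, and TNFRSF13B (-1.51 ± 0.29) and POU2F2 (-1.29 ± 0.10) fell. Of 19 germinal centre genes, 9 rose, 1 fell and 9 were not called, the same when adjusted over the list alone (median 0.36, adjusted p = 0.00666, and adjusted p = 0.419 with an estimated correlation). NEIL1 (1.84 ± 0.82) and ELL3 (1.52 ± 0.26) rose. Of 14 genes of antigen presentation by MHC class II, 9 rose, 1 fell and 4 were not called, the same when adjusted over the list alone (median 0.52, adjusted p = 0.00379, and adjusted p = 0.445 with an estimated correlation). HLA-DMB (1.52 ± 0.57) and HLA-DMA (1.36 ± 0.42) rose. The scanner's ratios ended the calls of ribosomal proteins (adjusted p = 0.0605) and B cell identity (0.111), and median centring that of germinal centre genes (median 0.63, adjusted p = 0.122). It moved the medians of ribosomal proteins (1.53), B cell identity (0.79) and MHC class II genes (0.91).

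NF-kB targets were lower in HBL1 under 15e by a small median. Of 44 targets, 18 fell, 4 rose and 22 were not called, and 19 fell and 5 rose when adjusted over the list alone (median -0.24, adjusted p = 0.0283, and adjusted p = 0.613 with an estimated correlation). EBI3 (-1.65 ± 0.75), TNF (-1.27 ± 0.81), CCL3 (-0.89 ± 0.45) and NFKBIA, which encodes IκBα, fell (-0.69 ± 0.36, adjusted p = 0.00516, probe at hg19 chromosome 14, 35870788 to 35870847). CCL4 was lower by at least 2.13-fold, since its inhibitor channel was not well above background (measured mean -1.15 ± 0.73). LTB, CD44 (0.92 ± 0.25) and IL6 (0.31 ± 0.10) rose. TNFAIP3 (-0.21 ± 0.12), BCL2A1 (0.19 ± 0.16), IRF4 (-0.30 ± 0.22) and IL10 (-0.44 ± 0.45) were not called. Of 30 immediate early and BCR feedback genes, 13 fell, 4 rose and 13 were not called, the same when adjusted over the list alone (median -0.26, adjusted p = 0.00666, and adjusted p = 0.435 with an estimated correlation). EGR2 (-2.10 ± 0.25) and NR4A3 (-1.71 ± 0.21) fell. PRDM1, a plasma cell factor (0.26 ± 0.05), and PIK3CA (0.47 ± 0.23) rose, IKBKB fell by 0.32 ± 0.12 (other probes up to 0.73), and PIK3CD was not called (0.27 ± 0.21). Median centring ended the call of the NF-kB targets (median -0.14, adjusted p = 0.162). It moved immediate early genes (-0.42), NFKBIA (-0.098), IL6 (0.17), KLF2 (-0.026), IKBKB (-0.074) and PRDM1 (0.094). Without 1 array, 7695 to 9448 genes were called, and calls were lost, with adjusted p from 0.0506 to 0.171, for KLF2 and IKBKB (12, 24 and 48 h), IL6 (24 and 48 h) and KLF2, PIK3CA and TNF (36 h).

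**Figure D1:**
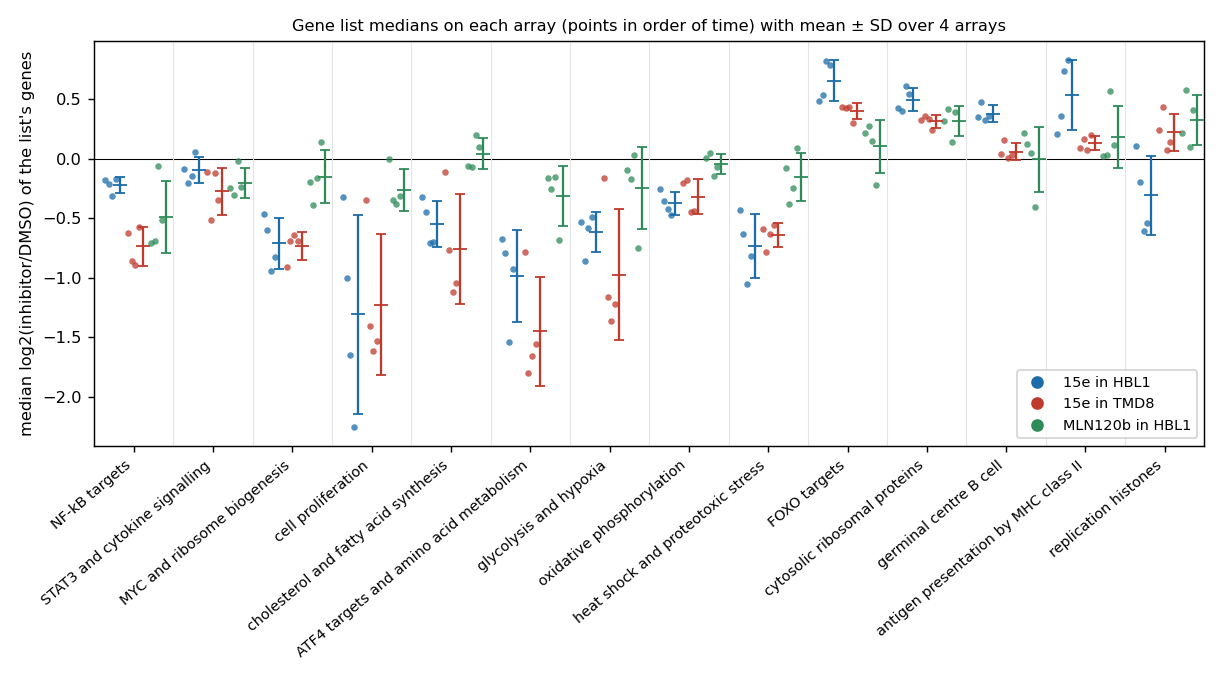
Median log2 ratio of inhibitor over DMSO of 14 gene lists (vertical axis, log2) on each array in order of time (points) with the mean ± SD of the 4 arrays of each group. Proliferation medians reach -2.25 in HBL1 and -1.62 in TMD8 under 15e. With median centring the oxidative phosphorylation list changes sign in each group. The MYC, proliferation, ATF4, glycolysis, heat shock and germinal centre lists do so under MLN120b.

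15e in TMD8 was measured at the same times. EGR2 had the lowest mean, -4.72 ± 0.68 (n = 4, adjusted p = 5.39e-07, probe at hg19 chromosome 10, 64571850 to 64571909). EGR1 (-3.02 ± 0.96), the cytokine gene TNF (-2.99 ± 0.73), PHGDH (-2.75 ± 1.15), BCAT1 (-2.68 ± 1.30), IL4I1 (-2.68 ± 0.72), asparagine synthetase ASNS (-2.65 ± 0.92) and HILPDA (-2.50 ± 1.37) were next. SUSD3 (2.70 ± 0.54), CEMIP (2.67 ± 0.72), RNU12 (2.32 ± 1.53), GNB3 (2.30 ± 1.16), GNG11 (2.20 ± 1.21), OSR2 (2.18 ± 0.41), HEPACAM2 (2.17 ± 1.19) and KCNH2 (2.14 ± 0.67) rose most. A total of 8861 genes were called, 4639 higher and 4222 lower (52.4% higher), and 1133 had a mean of at least 1 in size.

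NF-kB targets fell in TMD8 under 15e in 34 of 44 cases, rose in 3 and were not called in 7, the same when adjusted over the list alone. Their median was -0.67 (adjusted p = 2.92e-12, and adjusted p = 0.364 with an estimated correlation). The cytokine genes IL10 (-2.46 ± 0.37), IL6 (-1.72 ± 0.32) and EBI3 (-1.79 ± 0.99) fell, as did the chemokine genes CCL4 (-1.63 ± 0.37) and CCL3 (-1.38 ± 0.30). NFKBIA (-1.67 ± 0.42, adjusted p = 1.53e-05), IRF4 (-1.67 ± 0.41), TNFAIP3 (-1.17 ± 0.26), an inhibitor of NF-kB signalling, and BCL2A1 (-0.26 ± 0.05, but 0.12 with median centring) fell too. CD44 was not called (-0.13 ± 0.12), and LTB rose by 1.78 ± 1.65 with 3 of 4 arrays above 0. Of 21 STAT3 and cytokine genes, 11 fell, 5 rose and 5 were not called, the same when adjusted over the list alone (median -0.29, adjusted p = 0.0404, and adjusted p = 0.364 with an estimated correlation). The transcription factor gene BATF (-1.85 ± 0.40) was among those that fell.

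Growth and metabolic lists fell in TMD8 too, each with an adjusted p = 0.364 with an estimated correlation. Of 43 proliferation genes, 40 fell and 3 were not called, the same when adjusted over the list alone (median -1.30, adjusted p = 2.83e-13), with RRM2 at -1.70 ± 0.66 and BIRC5 at -1.67 ± 1.12. Of 35 MYC and ribosome biogenesis genes, 27 fell and 8 were not called, and 30 fell when adjusted over the list alone (median -0.69, adjusted p = 1.1e-12). ODC1 (-1.53 ± 0.15), PPAN (-1.47 ± 0.24) and MYC (-1.07 ± 0.39, other probes up to 0.22) fell. Of 35 ATF4 targets, 30 fell, 1 rose and 4 were not called, and 31 fell when adjusted over the list alone (median -1.45, adjusted p = 2.6e-15), with ATF5 at -2.06 ± 0.78. Of 31 cholesterol genes, 24 fell and 7 were not called, and 25 fell and 1 rose when adjusted over the list alone (median -0.74, adjusted p = 1.8e-08). ACAT2 (-1.60 ± 0.66) and MVK (-1.50 ± 0.75) fell. Of 30 glycolysis genes, 20 fell, 2 rose and 8 were not called, and 21 fell when adjusted over the list alone (median -1.02, adjusted p = 5.42e-07). Hexokinase HK2 (-2.37 ± 0.82) and SLC16A3 (-1.77 ± 1.09) fell. Of 18 heat shock genes, 12 fell, 2 rose and 4 were not called, the same when adjusted over the list alone (median -0.59, adjusted p = 6.1e-05), with HSPD1 at -1.31 ± 0.47 and HSP90AB1 at -1.19 ± 0.26. Of 33 oxidative phosphorylation genes, 19 fell, 3 rose and 11 were not called, the same when adjusted over the list alone (median -0.40, 0.02 and so opposite in sign with median centring, adjusted p = 3.33e-05), with ATP5F1B at -0.94 ± 0.14 and NDUFS1 at -0.68 ± 0.10. Median centring ended the calls of heat shock (median -0.16, adjusted p = 0.0547) and oxidative phosphorylation genes (0.995), and moved HSPD1 (-0.59), ATP5F1B (-0.43), NDUFS1 (-0.39) and ODC1 (-1.0).

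FOXO targets and ribosomal protein genes rose in TMD8. Of 28 FOXO targets, 15 rose, 6 fell and 7 were not called, and 16 rose when adjusted over the list alone (median 0.36, adjusted p = 0.0384, and adjusted p = 0.501 with an estimated correlation). GADD45A (1.36 ± 0.40), TXNIP (1.19 ± 0.24) and FOXO1 (1.18 ± 0.32) rose, KLF2 (-1.25 ± 0.58) and CCND2 (-0.75 ± 0.30) fell, and BCL6 (0.32 ± 0.46) and PIK3IP1 (0.24 ± 0.18) were not called. Of 41 ribosomal protein genes, 25 rose and 16 were not called, and 26 rose when adjusted over the list alone (median 0.38, adjusted p = 5.42e-07, and adjusted p = 0.364 with an estimated correlation). RPL30 (0.65 ± 0.15) rose, but with the scanner's ratios the list was not called (adjusted p = 0.788), and its median was 1.21 with median centring. PRDM1 (0.38 ± 0.16) and PIK3CA (0.40 ± 0.43) rose, and IKBKB (-0.14 ± 0.27) and PIK3CD (-0.14 ± 0.19) were not called. The FOXO call was lost without 12 h (adjusted p = 0.0823), with median centring (0.0551), the scanner's ratios (0.0563) or the mean over probes (0.0559), and the STAT3 call without 12 h (0.0564) or 24 h (0.0593). Without 1 array, 7025 to 8871 genes were called, and BCL2A1 (24, 36 and 48 h), PIK3CA (36 and 48 h) and LTB (48 h) lost their calls (adjusted p from 0.0525 to 0.176).

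The responses of the lines to 15e were then set against each other. Of 44 NF-kB targets, 18 were lower in TMD8 than in HBL1 and 26 not called, and 20 were lower when adjusted over the list alone (median difference -0.49, adjusted p = 2.17e-08, and adjusted p = 0.628 with an estimated correlation). IL6 (-1.72 ± 0.32 in TMD8, 0.31 ± 0.10 in HBL1, difference -2.03, adjusted p = 1.08e-05), IL10 (difference -2.02), TNF (-1.71) and IRF4 (-1.37) differed most. CD44 (-1.05), NFKBIA (-0.98, adjusted p = 0.0159), TNFAIP3 (-0.96) and BCL2A1 (-0.44) were lower too, and CCL3 (-0.49) was not called. No difference is read for CCL4, whose HBL1 value is a bound. The list's array medians averaged -0.74 ± 0.16 in TMD8 and -0.22 ± 0.07 in HBL1. Over splits that mix the times, this difference of -0.52 had the smallest possible 2-sided exact permutation p, 0.0286. Adjusted over the 25 lists it was 0.0794, as for p53 targets.

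**Figure D2:**
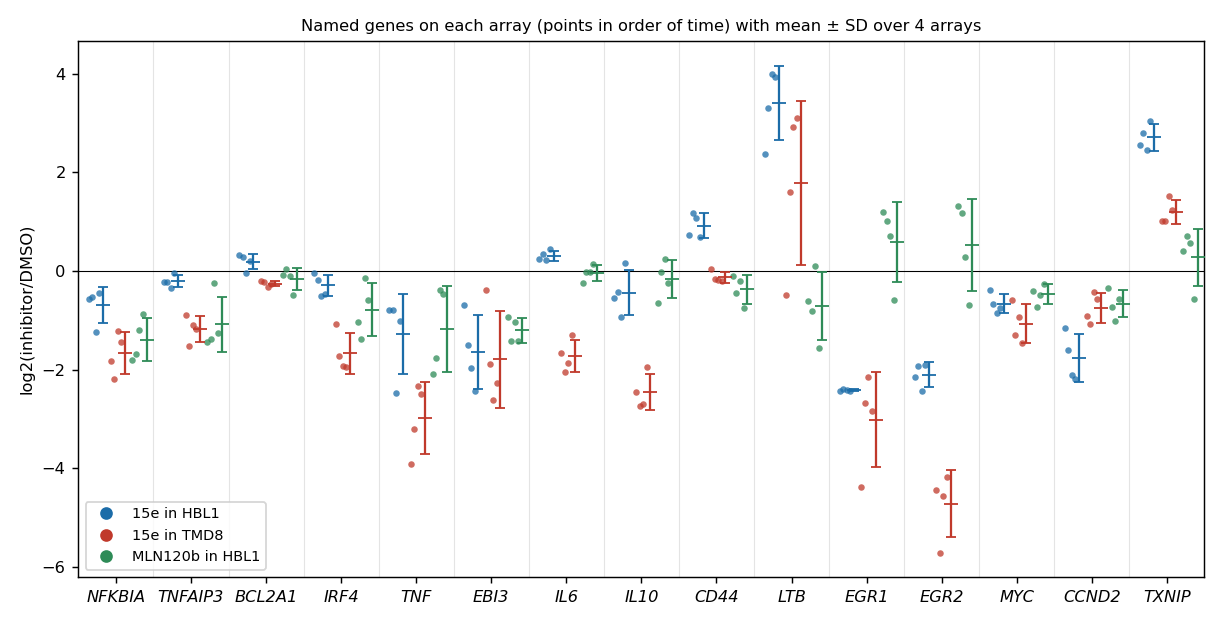
Log2 ratio of inhibitor over DMSO of 15 named genes (vertical axis, log2) on each array (points) with the mean ± SD of 4 arrays, for 15e in HBL1, 15e in TMD8 and MLN120b in HBL1. NFKBIA has means of -0.69, -1.67 and -1.40, and with median centring its mean turns positive in HBL1 under both inhibitors (0.23 and 0.11, before the shifts of all genes by 0.33 and 0.66 are taken off).

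Germinal centre genes were lower in TMD8 than in HBL1 in 8 of 19 cases, higher in 1 and not called in 10, and 11 were lower and 1 higher when adjusted over the list alone (median difference -0.47, adjusted p = 0.000596, and adjusted p = 0.601 with an estimated correlation). LMO2 fell by 2.09 ± 0.30 in TMD8, and in HBL1 its DMSO channel was not above background. Of 14 MHC class II genes, 3 were lower and 11 not called, and 8 were lower and 1 higher when adjusted over the list alone (median difference -0.49, adjusted p = 0.00165, and adjusted p = 0.791 with an estimated correlation). HLA-DQA1 (-0.77) and CIITA (-0.71, with probes of opposite sign in HBL1) were among them. Of 28 replication histone genes, 10 were higher in TMD8, 3 lower and 15 not called, and 13 were higher and 3 lower when adjusted over the list alone (median difference 0.51, adjusted p = 0.00231, and adjusted p = 0.791 with an estimated correlation). H4C8 (0.82 ± 0.24 in TMD8, -0.38 ± 0.36 in HBL1) and H2BC5 (difference 1.56, with probes of opposite sign in HBL1) were higher, and H2BC12 was lower (-0.28 ± 0.07 in TMD8, 1.73 ± 0.56 in HBL1). Of 41 ribosomal protein genes, 6 were lower and 35 not called, and 5 were lower when adjusted over the list alone (median difference -0.23, adjusted p = 0.0133, and adjusted p = 0.839 with an estimated correlation). RPL4 (-0.50) was lower, and the scanner's ratios ended the list's call (adjusted p = 0.0827). With median centring its median was -0.49.

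FOXO targets were lower in TMD8 in 4 of 28 cases, higher in 3 and not called in 21, and 10 were lower and 3 higher when adjusted over the list alone (median difference -0.24, adjusted p = 0.0355, and adjusted p = 0.791 with an estimated correlation). TSC22D3 (-0.33 ± 0.30 in TMD8, 1.41 ± 0.15 in HBL1), TXNIP (difference -1.51) and PIK3IP1 (-0.78) were lower, and GADD45A (1.09) and CCND2 (1.02, or 0.66 with median centring) higher. Of 35 ATF4 targets, 4 were lower, 2 higher and 29 not called, and 6 were lower and 2 higher when adjusted over the list alone (median difference -0.33, adjusted p = 0.0179, and adjusted p = 0.893 with an estimated correlation). TRIB3 (-1.50) and ATF5 (-1.40) were lower and ATF3 higher (1.46). Of 30 interferon response genes, 6 were lower, 1 higher and 23 not called, and 7 were lower and 1 higher when adjusted over the list alone (median difference -0.18, adjusted p = 0.0456, and adjusted p = 0.862 with an estimated correlation). IFI27 (-2.04 ± 0.30 in TMD8, -0.19 ± 0.15 in HBL1) and IRF7 (difference -1.59) were lower. Proliferation (0 of 43 genes, median difference 0.08, adjusted p = 0.425) and MYC and ribosome biogenesis (1 of 35 higher, 0.07, adjusted p = 0.513) were not called. The interferon call was lost without HBL1 at 12 h (adjusted p = 0.167) or 24 h (0.0761), TMD8 at 12 h (0.325) or with median centring (0.101), and the FOXO call without HBL1 at 36 h (0.0713), TMD8 at 12 h (0.0563) or 24 h (0.0725) or with the scanner's ratios (0.101). The ATF4 call was lost without HBL1 at 12 h (0.170) or 24 h (0.102), TMD8 at 24 h (0.0983) or 36 h (0.0737) or with median centring (0.0833). Fry kept the calls between lines of NF-kB targets (0.0128) and germinal centre genes (0.00469) alone (others 0.0842 to 0.442).

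By gene, TNFRSF21 rose in TMD8 (1.98 ± 0.67) and fell in HBL1 (-1.40 ± 0.14), the largest difference upwards (3.38). CTSF and STRA8, which rose in HBL1, were not above background in TMD8 (CTSF in the DMSO channel). UCHL1 fell in HBL1 and was not above background in TMD8, and HEPACAM2 and OSR2 rose in TMD8 and were not above background in HBL1, so no difference is read for these 5 genes. EGR2 (-2.62), ID2 (-1.92 ± 0.32 in TMD8, 0.69 ± 0.15 in HBL1, difference -2.61), ARHGEF10 (-2.60) and CHST12 (-2.44) were lower in TMD8. RGS1 (2.36) and RNU12 (2.14) were higher. MYC (-0.41), PRDM1 (0.12), BCL6 (-0.85), KLF2 (-0.74), IKBKB (0.17), PIK3CD (-0.41) and PIK3CA (-0.07) were not called. In all, 3772 genes differed, 2058 higher and 1714 lower in TMD8 (54.6% higher). The count was 2385 without HBL1 at 48 h and 1632 with median centring. The arrays of the lines did not overlap for 4996 of 20562 genes (24.3%, against 2.86% by chance). Among the named genes, calls were lost without HBL1 at 12 or 24 h (BCL2A1, RGS1, TNF), 36 h (RGS1, ATF3, RPL4) or 48 h (these, NFKBIA, BCL2A1 and TNF), and without TMD8 at 24 h (NFKBIA, RGS1, TNF) or 36 or 48 h (BCL2A1, RGS1), with adjusted p from 0.0502 to 0.102.

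Most genes called in both lines under 15e moved the same way. Of 20562 genes, 2603 rose in both lines and 2809 fell in both, against 1197 and 990 for independent lists, and 216 were called in opposite directions, against 2177. The mean log2 ratios of the lines correlated across genes with r = 0.643 and a Spearman rho of 0.646. For 15e and MLN120b in HBL1, 1282 genes rose and 502 fell under both (549 and 203 for independent lists), with 84 opposite (723) and r = 0.551 (rho 0.566). For 15e in TMD8 and MLN120b in HBL1 the counts were 937, 432 and 93 (480, 178 and 633), with r = 0.433 (rho 0.450). Genes are not independent replicates, and all arrays shared 1 dye orientation, so gene-specific dye effects add to these overlaps. The labels do not say whether the HBL1 experiments shared DMSO samples, which could add to theirs.

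**Figure D3:**
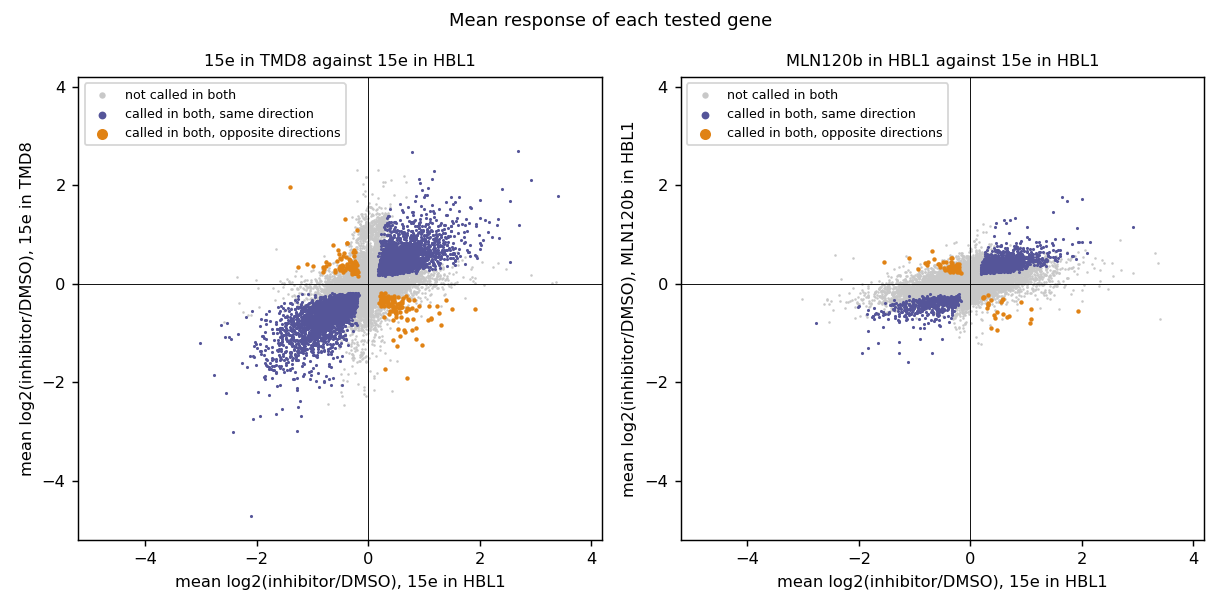
Mean log2 ratio of each gene for 15e in TMD8 and for MLN120b in HBL1 against 15e in HBL1 (both axes log2, 4 arrays per mean), with genes called in both comparisons coloured by whether they moved the same or opposite ways. The correlations across genes are 0.643 and 0.551.

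MLN120b was measured in HBL1 to learn which genes follow IKKβ. NFKBIA fell by 1.40 ± 0.43 (n = 4, adjusted p = 0.00309), and SOCS3, a feedback inhibitor of STAT3 signalling, had the lowest mean, -1.41 ± 0.63. IL4I1 (-1.41 ± 0.52), LRRC32 (-1.30 ± 0.95), TNFAIP2 (-1.22 ± 0.57), EBI3 (-1.20 ± 0.25), ADAM8 (-1.20 ± 0.31) and TNF (-1.18 ± 0.87) were next. CRYM rose by 1.77 ± 0.89 and FST by 1.46 ± 0.70. The other 6 of the 8 highest genes encode histone H2B: H2BC12 (1.69 ± 0.96), H2BC9 (1.35 ± 0.68), H2BC13 (1.30 ± 0.62), H2BC7 (1.30 ± 0.59), H2BC6 (1.24 ± 0.60) and H2BC17 (1.23 ± 0.60). A total of 2995 genes were called, 2128 higher and 867 lower, of which 32 had a mean of at least 1 in size.

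NF-kB targets fell under MLN120b in 21 of 44 cases and 23 were not called, and 28 fell and 1 rose when adjusted over the list alone (median -0.50, adjusted p = 3.18e-15, and adjusted p = 0.285 with an estimated correlation). TNFAIP3 (-1.08 ± 0.56), BIRC3 (-0.94 ± 0.30), IRF4 (-0.79 ± 0.54) and CD44 (-0.37 ± 0.29) were among them. CCL4 (0.56 ± 0.44), CCL3 (0.26 ± 0.30), BCL2A1 (-0.16 ± 0.23), IL10 (-0.17 ± 0.38) and IL6 (-0.04 ± 0.16) were not called. Of 21 STAT3 and cytokine genes, 3 fell and 18 were not called, and 5 fell when adjusted over the list alone (median -0.19, adjusted p = 0.000191, and adjusted p = 0.285 with an estimated correlation). They were SOCS3, BATF (-0.88 ± 0.36) and STAT3 (-0.83 ± 0.57). Of 30 interferon response genes, 3 fell and 27 were not called, the same when adjusted over the list alone (median -0.15, adjusted p = 0.000319, and adjusted p = 0.503 with an estimated correlation). IFI44L (-0.80 ± 0.59) and IFIH1 (-0.74 ± 0.50) fell. Of 27 BCL2 family genes and caspase inhibitors, 5 fell, 1 rose and 21 were not called, and 6 fell and 1 rose when adjusted over the list alone (median -0.04, 0.50 and so opposite in sign with median centring, adjusted p = 0.0144, and adjusted p = 0.503 with an estimated correlation). BIRC3 and BCL2L1 (-0.64 ± 0.38) fell, and the list's call was lost without the 48 h array (adjusted p = 0.131). Median centring left the NF-kB targets at -0.28 (adjusted p = 0.228), the STAT3 list at -0.28 (0.397) and the interferon list at -0.29 (0.996), none of them called. Fry called neither the interferon (0.255) nor the BCL2 family list (0.200).

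Ribosomal protein and histone genes rose under MLN120b. Of 41 ribosomal protein genes, 21 rose and 20 were not called, and 31 rose when adjusted over the list alone (median 0.29, adjusted p = 9.67e-11, and adjusted p = 0.285 with an estimated correlation). RPS14 (0.73 ± 0.25) and RPS6 (0.65 ± 0.18) rose, and the scanner's ratios ended the list's call (adjusted p = 0.129). With median centring its median was 1.56. Of 28 replication histone genes, 10 rose and 18 were not called, and 12 rose when adjusted over the list alone (median 0.32, 0.84 with median centring, adjusted p = 2.17e-05, and adjusted p = 0.503 with an estimated correlation).

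Growth and metabolic lists were lower under MLN120b with few members called, and fry called none (adjusted p from 0.210 to 0.501). Each changed sign with median centring, which leaves in dye effects that vary with brightness. Of 35 ATF4 targets, 5 fell and 30 were not called, the same when adjusted over the list alone (median -0.31 against 0.27, adjusted p = 2.97e-08, and adjusted p = 0.503 with an estimated correlation). SLC1A5 was at -0.95 ± 0.34 and MTHFD2 at -0.61 ± 0.17. Of 30 glycolysis genes, ENO1 (-0.66 ± 0.20) fell and 29 were not called, the same when adjusted over the list alone (median -0.22 against 0.43, adjusted p = 2.93e-05, and adjusted p = 0.503 with an estimated correlation). Of 35 MYC and ribosome biogenesis genes, 2 fell and 33 were not called, and 0 fell when adjusted over the list alone (median -0.18 against 0.50, adjusted p = 7.76e-06, and adjusted p = 0.511 with an estimated correlation). Of 43 proliferation genes, 2 fell, among them MCM7 (-0.60 ± 0.27), and 41 were not called, and 0 fell when adjusted over the list alone (median -0.25 against 0.42, adjusted p = 7.37e-05, and adjusted p = 0.692 with an estimated correlation). Of 18 heat shock genes limma called 0, also when adjusted over the list alone (median -0.13 against 0.63, adjusted p = 0.042, and adjusted p = 0.621 with an estimated correlation), and the list's call was lost without the array at 12 h (0.294) or 24 h (0.196). MYC (-0.47 ± 0.20, other probes up to 0.04) and CCND2 (-0.66 ± 0.28) fell. With median centring NFKBIA (-0.55), IRF4 (-0.26), BIRC3 (-0.26), EBI3 (-0.72), STAT3 (-0.46) and SLC1A5 (-0.59) were closer to 0. MYC (0.39), CCND2 (0.34), CD44 (0.55), BATF (0.12), MCM7 (0.45), MTHFD2 (0.27) and ENO1 (0.40) changed sign. PRDM1 was not above background. PIK3IP1 (-0.07 ± 0.30), BCL6 (0.12 ± 0.65), KLF2 (-0.24 ± 0.51), IKBKB (-0.14 ± 0.17), PIK3CD (-0.26 ± 0.37) and PIK3CA (0.01 ± 0.08) were not called.

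The MLN120b array at 24 h stood apart. Its log2 ratios correlated across genes with those of the other MLN120b arrays at 0.18 to 0.34 and with the HBL1 arrays of 15e at 0.38 to 0.46. Its median for NF-kB targets was -0.06, against -0.71, -0.69 and -0.51 at 6, 12 and 48 h, and relative to all genes it was -0.33 with the scanner's ratios, -0.26 without background correction and 0.56 with median centring. The count of called genes was 566, 119, 3754 and 869 without the arrays at 6, 12, 24 and 48 h, and 3 when the MLN120b arrays alone set the spread. Of the 33 named genes called, 9 lost the call without 6 h (IRF4, MYC, CD44, LRRC32, EBI3, TNF, IFI44L, IFIH1 and MCM7), 20 without 12 h and 3 without 24 h (MYC, CCND2 and MCM7). Without 48 h, MYC, CD44, CCND2, LRRC32, EBI3, TNF, STAT3, MCM7 and ENO1 lost it. The adjusted p of lost calls lay between 0.0510 and 0.178, and NFKBIA, TNFAIP3, TNFAIP2 and ADAM8 kept theirs without any 1 of the 4 arrays. Without 24 h, KLF2 (15e in HBL1), RGS1 (between lines) and the trends of SHMT2 (HBL1) and PHGDH (TMD8) lost their calls too.

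**Figure D4:**
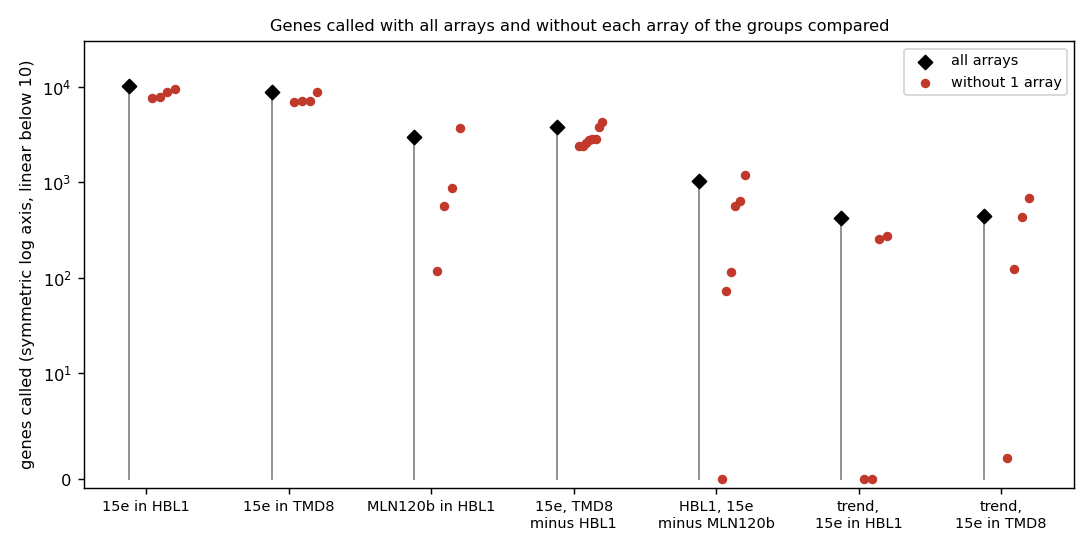
Number of genes called in each comparison with all arrays and without each array in turn (symmetric log axis, counts of genes). The MLN120b count goes from 2995 to 119 without the 12 h array, and the count for the difference between inhibitors from 1032 to 0 without the 24 h array of 15e.

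Genes lowered by MLN120b were followed under 15e. Under MLN120b 215 genes, 17 of them in the NF-kB list, were called with a mean of -0.5 or lower. Under 15e in HBL1 144 of them fell, 12 rose and 59 were not called (median -0.60, adjusted p = 3.77e-20, and adjusted p = 0.161 with an estimated correlation). In TMD8 147 fell, 10 rose and 58 were not called (median -0.73, adjusted p = 3.18e-23, and adjusted p = 0.161 with an estimated correlation), and 123 fell in both lines. The set was chosen on these arrays, which share a dye orientation, so it is not independent evidence of its direction. Over time, the set fell further in HBL1 under 15e (3 of 215 slopes called, adjusted p = 0.000107, adjusted p = 0.651 with an estimated correlation, and fry 0.566). No trend of the set was called in TMD8 (adjusted p = 0.396), but without the 12 h array it was called in the opposite direction (0.00577) and without the 48 h array it was called as well (0.0291).

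The inhibitors were compared in HBL1 at 12, 24 and 48 h, with 3 arrays each. LTB differed most, 3.20 ± 0.79 with 15e against -0.75 ± 0.84 with MLN120b (n = 3, difference 3.96, adjusted p = 0.0154). CTSF (2.79), NLRP7 (2.61), TXNIP (2.56), COL18A1 (2.38) and STRA8 (2.34) were also higher with 15e. SH2D5 (-2.83), EGR1 (-2.42 ± 0.03 against 0.38 ± 0.85, difference -2.80), LRRC20 (-2.28), EGR2 (-2.25), UCHL1 (-1.94) and MYB (-1.78) were lower. In all 1032 genes differed, 350 higher and 682 lower with 15e, and 380 by at least 1 in size. The arrays did not overlap for 30.6% of genes, where chance gives 10%.

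Several lists lay higher with 15e than with MLN120b. Of 44 NF-kB targets, 4 were higher, 2 lower and 38 not called, and 6 were higher and 3 lower when adjusted over the list alone (median difference 0.15, -0.03 and so opposite in sign with median centring, adjusted p = 0.00815, and adjusted p = 0.554 with an estimated correlation). TNFAIP2 (1.35), BIRC3 (0.52 ± 0.07 against -0.82 ± 0.23) and CD44 (0.86 ± 0.27 against -0.47 ± 0.27) were higher and CCL3 (-0.95) lower, and for CCL4, a bound under 15e, no difference is read. NFKBIA (0.74, adjusted p = 0.0681), TNFAIP3 (0.80), IRF4 (0.48) and MYC (-0.11) were not called. Of 30 interferon response genes, 5 were higher and 25 not called, and 11 were higher when adjusted over the list alone (median difference 0.25, adjusted p = 1.3e-05, and adjusted p = 0.525 with an estimated correlation), with IRF7 at 1.51 and OAS1 at 1.27. Of 28 FOXO targets, 7 were higher, 1 lower (CDKN1A, -1.36) and 20 not called, and 11 were higher and 4 lower when adjusted over the list alone (median difference 0.41, adjusted p = 2.11e-05, and adjusted p = 0.525 with an estimated correlation). TSC22D3 (1.69) and PIK3IP1 (1.14) were higher. Of 19 germinal centre genes, 5 were higher and 14 not called, and 6 were higher when adjusted over the list alone (median difference 0.47, adjusted p = 0.000168, and adjusted p = 0.525 with an estimated correlation). NEIL1 (1.86) was higher. Of 35 B cell identity genes, 2 were higher, 2 lower and 31 not called, and 5 were higher and 2 lower when adjusted over the list alone (median difference 0.26, -0.04 and so opposite in sign with median centring, adjusted p = 0.0017, and adjusted p = 0.525 with an estimated correlation). Of 41 ribosomal protein genes, RPS20 (0.66) was higher and 40 not called, the same when adjusted over the list alone (median difference 0.15, -0.37 and so opposite in sign with median centring, adjusted p = 0.00394, and adjusted p = 0.554 with an estimated correlation). Of 14 MHC class II genes limma called 0, also when adjusted over the list alone (median difference 0.29, -0.20 and so opposite in sign with median centring, adjusted p = 0.0474, and adjusted p = 0.592 with an estimated correlation).

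Growth and metabolic lists lay lower with 15e than with MLN120b. Of 43 proliferation genes, 1 was lower and 42 not called, and 8 were lower when adjusted over the list alone (median difference -0.83, adjusted p = 3.18e-07, and adjusted p = 0.554 with an estimated correlation). The lists below, glycolysis apart, had an adjusted p = 0.525 with an estimated correlation. Of 35 MYC and ribosome biogenesis genes, 5 were lower, among them ODC1 (-1.46) and MRTO4 (-1.07), and 30 not called, and 17 were lower when adjusted over the list alone (median difference -0.51, adjusted p = 2.04e-07). Replication histones (1 of 28 lower, 27 not called, 14 adjusted over the list alone, median difference -0.73, adjusted p = 2.04e-07) and cholesterol genes (4 of 31 lower, 27 not called, 13 adjusted over the list alone, median difference -0.45, adjusted p = 2.04e-07) followed. DHCR7 (-1.15) and ACAT2 (-1.03) were lower. Of 35 ATF4 targets, 7 were lower, among them ATF3 (-1.66) and ALDH1L2 (-1.32), and 28 not called, and 10 were lower when adjusted over the list alone (median difference -0.50, adjusted p = 3.05e-05). Of 33 oxidative phosphorylation genes, 3 were lower, among them ATP5MC1 (-0.98), and 30 not called, and 9 were lower when adjusted over the list alone (median difference -0.22, adjusted p = 0.000437). Of 30 immediate early genes, 7 were lower, 1 higher and 22 not called, and 10 were lower and 2 higher when adjusted over the list alone (median difference -0.29, adjusted p = 0.00312). Of 18 heat shock genes, HSPB1 (-1.43) was lower and 17 not called, and 8 were lower and 1 higher when adjusted over the list alone (median difference -0.43, adjusted p = 0.00656). Of 30 glycolysis genes, 4 were lower, 1 higher and 25 not called, and 10 were lower and 1 higher when adjusted over the list alone (median difference -0.36, adjusted p = 0.00741, and adjusted p = 0.575 with an estimated correlation).

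The count of genes that differed between inhibitors was 0 by limma without the 24 h array of 15e, 1200 without its 12 h array and 116 without its 48 h array. It was 563, 643 and 72 without the MLN120b arrays at 12, 24 and 48 h, and 622 with the time point as a block. Of the 36 named genes called, 3 (CCL3, TNFAIP2 and RPS20), 36 and 22 lost the call without 15e at 12, 24 and 48 h, and 12, 11 and 27 without MLN120b at these times (adjusted p from 0.0503 to 0.172). List calls were lost for NF-kB targets (without MLN120b at 12 h, 0.215, median centring, 0.878), glycolysis (MLN120b 24 h, 0.240, scanner's ratios, 0.0686), ribosomal proteins (MLN120b 24 h, 0.194, scanner's ratios, 0.497) and MHC class II (15e 48 h, 0.524, MLN120b 12 h, 0.215, and 48 h, 0.136). Median centring also ended those of B cell identity (0.905) and immediate early genes (0.0915), and the scanner's ratios that of heat shock (0.0675). Median centring moved the lists of interferon (0.45), MYC (-1.06), proliferation (-1.36), cholesterol (-0.92), ATF4 (-0.87), oxidative phosphorylation (-0.85), immediate early (-0.46), heat shock (-0.95) and glycolysis genes (-0.64), and BIRC3 (0.89) and RPS20 (0.11). Fry kept none of the list calls between inhibitors (0, adjusted p from 0.134 to 0.590).

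Time trends were fitted as slopes per doubling of the hours. In HBL1 under 15e the mitotic cyclin gene CCNB1 had the steepest fall, -1.27 ± 0.16 (SE, adjusted p = 0.00596), then TK1 (-1.21 ± 0.13), the cyclin gene CCNA2 (-1.20 ± 0.19) and RRM2 (-1.20 ± 0.21). MED18 (1.1 ± 0.23), STRA8 (1.09 ± 0.18), COL18A1 (1.04 ± 0.09) and NSG1 (1.04 ± 0.15) rose with time. Of 43 proliferation genes, 33 fell with time and 10 were not called, and 40 fell when adjusted over the list alone (median slope -1.0, adjusted p = 4.52e-55, and adjusted p = 0.12 with an estimated correlation), the only trend list (1) that fry called (0.00799). Of 28 replication histones, 7 fell and 21 were not called, and 15 fell and 1 rose when adjusted over the list alone (median slope -0.30, adjusted p = 4.37e-08, and adjusted p = 0.54 with an estimated correlation), with H4C3 at -1.07 and H1-5 at -0.98. Of 31 cholesterol genes, FADS2 (-0.58) fell and 30 were not called, and 2 fell when adjusted over the list alone (median slope -0.22, adjusted p = 1.21e-07, and adjusted p = 0.54 with an estimated correlation). Of 35 ATF4 targets, SHMT2 (-0.86) and ATF3 (-0.74) fell and 33 were not called, the same when adjusted over the list alone (median slope -0.23, adjusted p = 2.48e-06, and adjusted p = 0.63 with an estimated correlation). Of 18 heat shock genes, HSPA8 (-0.62) fell and 17 were not called, the same when adjusted over the list alone (median slope -0.16, adjusted p = 0.0012, and adjusted p = 0.63 with an estimated correlation). Limma called 0 members, also when adjusted over the list alone, of the MYC list (35 genes, median slope -0.22, adjusted p = 8.22e-07, and adjusted p = 0.63 with an estimated correlation) and the oxidative phosphorylation list (33, -0.10, adjusted p = 0.00595, and adjusted p = 0.63 with an estimated correlation). The same held for the MHC class II list, which rose with time (14 genes, median slope 0.38, adjusted p = 3.95e-07, and adjusted p = 0.54 with an estimated correlation). Of 423 genes with a trend, 97 rose and 326 fell, and the count was 0 without the 12 h or the 48 h array, so that all 14 named trends lost their calls, 272 without 24 h (ATF3, 0.0501) and 255 without 36 h (MED18, FADS2, SHMT2, ATF3 and HSPA8, 0.0595 to 0.0985). The heat shock call was lost without 12 h (0.0888), and the oxidative phosphorylation call with median centring (0.303, median slope -0.05 relative to all genes) and the scanner's ratios (0.0533).

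In TMD8 under 15e, S100A4 (-1.69 ± 0.27, adjusted p = 0.0149), TOX2 (-1.59), TUBB2B (-1.49) and CAV1 (-1.41) fell with time. LTB (1.88 ± 0.26, adjusted p = 0.0132), RNU12 (1.62), NLRP7 (1.49 ± 0.17) and SNAI2 (1.32) rose. Of 43 proliferation genes, 21 fell and 22 were not called, and 28 fell when adjusted over the list alone (median slope -0.70, adjusted p = 9.95e-22, and adjusted p = 0.403 with an estimated correlation), with BIRC5 at -1.18. Of 31 cholesterol genes, 7 fell and 24 were not called, and 18 fell when adjusted over the list alone (median slope -0.47, adjusted p = 5.6e-16, and adjusted p = 0.403 with an estimated correlation), with INSIG1 at -0.96 and DHCR7 at -0.88. Of 35 ATF4 targets, 3 fell and 32 were not called, and 9 fell when adjusted over the list alone (median slope -0.44, adjusted p = 4.51e-10, and adjusted p = 0.537 with an estimated correlation), with PHGDH at -1.11. Of 30 glycolysis and hypoxia genes, 6 fell and 24 were not called, and 13 fell when adjusted over the list alone (median slope -0.45, adjusted p = 1.85e-09, and adjusted p = 0.403 with an estimated correlation), with ANKRD37 at -1.34. Limma called 0 of 33 oxidative phosphorylation genes, also when adjusted over the list alone (median slope -0.12, adjusted p = 0.000813, and adjusted p = 0.403 with an estimated correlation). Of 30 interferon response genes, ISG20 (0.93) rose and 29 were not called, and 2 rose when adjusted over the list alone (median slope 0.13, adjusted p = 0.00141, and adjusted p = 0.403 with an estimated correlation), a call lost with median centring (0.365, median slope 0.06), which moved ATF4 targets (-0.68), glycolysis (-0.84) and oxidative phosphorylation (-0.44). Of 444 genes, 172 rose and 272 fell, and the count was 2 without the 12 h array, where all 16 named trends lost their calls, 690 without 24 h and 124 without 36 h (SNAI2, BIRC5, PHGDH, SHMT2 and ANKRD37, 0.0597 to 0.109). The calls of the interferon (0.347), cholesterol (0.362), ATF4 (0.0758, opposite in sign) and glycolysis lists (0.924) were also lost without 12 h, and fry kept none of the 6 (0.0594 to 0.284).

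Under MLN120b limma called no gene with a time trend (0, with 1755 at an unadjusted p under 0.05), and fry called none of the lists (0). Camera called 12 lists, with adjusted p = 0.235 to 0.667 with an estimated correlation, in which limma called 0 members. The lowest p was that of the 30 interferon response genes, whose medians went from -0.28 at 6 h to 0.06 at 48 h (0 called also when adjusted over the list alone, median slope 0.15, adjusted p = 2.49e-08, and adjusted p = 0.235 with an estimated correlation), a call lost with median centring (0.494). Of 28 FOXO targets 0 were called, also when adjusted over the list alone (median slope -0.17, adjusted p = 4.4e-06, and adjusted p = 0.335 with an estimated correlation), and this call was lost without the 48 h array (0.429). Slopes upwards had the lists of MYC and ribosome biogenesis (median slope 0.15, adjusted p = 1.51e-06, and adjusted p = 0.651 with an estimated correlation), NF-kB targets (0.10, adjusted p = 0.00022, and the same p = 0.651), MHC class II (0.10, 0.0109, p = 0.651), histones (0.05, 0.00022, p = 0.651) and cholesterol (0.06, 0.0124, p = 0.667). Slopes downwards had glycolysis (-0.15, adjusted p = 7.67e-06, and adjusted p = 0.651 with an estimated correlation), ATF4 targets (-0.14, 3.89e-06, p = 0.651), germinal centre (-0.11, 0.00022, p = 0.335), proliferation (-0.10, 0.00179, p = 0.667) and immediate early genes (-0.08, 0.000874, p = 0.608). When adjusted over the list alone, 8 histone genes rose and 2 fell, 1 ATF4 target fell, 3 germinal centre genes fell, and 1 immediate early gene rose and 5 fell. The calls of NF-kB targets, histones, cholesterol, MHC class II and proliferation were lost without the 6 h array (0.0697 to 0.778), and those of histones, ATF4, germinal centre, immediate early, MYC and glycolysis without the 48 h array (0.144 to 0.617), the proliferation, MYC and glycolysis lists taking the opposite sign. Those of cholesterol (0.108) and MHC class II (0.244) were lost without the 24 h array too. Median slopes moved with median centring for interferon (0.025), proliferation (-0.037), histones (0.10), cholesterol (0.14), ATF4 (-0.079), glycolysis (-0.082) and MHC class II (0.15).

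**Figure D5:**
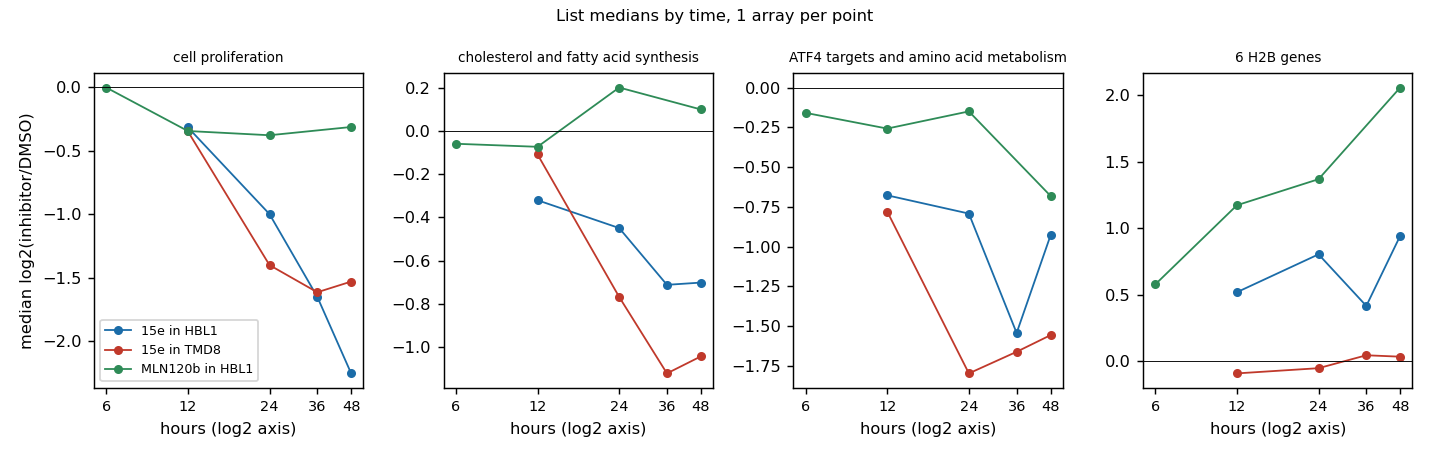
Median log2 ratio (vertical axes, log2, with separate scales) of proliferation genes, cholesterol genes, ATF4 targets and 6 H2B genes against hours of treatment (log axis) for the 3 groups. Proliferation medians go from -0.32 at 12 h to -2.25 at 48 h with 15e in HBL1. With median centring those of proliferation genes and ATF4 targets under MLN120b change sign.

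Further lists were called by camera in none of the 3 groups. Fry, which does not compare a list with other genes, called some of them (adjusted p): plasma cell genes (0.0218, downwards) in HBL1 under 15e, and upwards p53 targets (0.0132 there, 0.0432 under MLN120b), T and NK cell markers (0.00556 in HBL1, 0.00252 in TMD8 under 15e), myeloid markers (0.0159 under MLN120b) and erythroid, stromal and epithelial markers (0.00034, 0.00028 and 0.0146 in the 3 groups). Of 27 plasma cell genes, 4 rose and 11 fell under 15e in HBL1 (adjusted p = 0.193), 10 rose and 8 fell in TMD8 (0.899), and 1 fell under MLN120b (0.189). Of 25 p53 targets, 9 rose and 5 fell, 6 rose and 7 fell, and 6 rose and 1 fell in these groups (adjusted p = 0.673, 0.586 and 0.619). Of 33 components of PI3K, AKT and mTOR signalling, 11 rose and 8 fell, 6 rose and 10 fell, and 2 rose and 1 fell (adjusted p = 0.844, 0.399 and 0.261). Of 28 NF-kB pathway components, 10 rose and 6 fell, 7 rose and 7 fell, and 2 rose and 2 fell (adjusted p = 0.844, 0.645 and 0.261). When adjusted over the list alone, 1 gene more or fewer was called in some of these lists: 6 p53 targets fell in HBL1, 8 fell in TMD8 and 7 rose under MLN120b, 11 NF-kB pathway components rose in HBL1, and 1 PI3K component rose under MLN120b. Of 12 T and NK cell markers, 4 rose and 2 fell under 15e in HBL1 (median -0.01 but mean 0.26, adjusted p = 0.535), 4 rose and 1 fell in TMD8 (0.234) and 1 rose under MLN120b (0.907). Of 6 myeloid markers, 1, 1 and 3 rose, or 0, 1 and 4 when adjusted over the list alone (adjusted p = 0.965, 0.845 and 0.103). Of 15 erythroid, stromal and epithelial markers, 3 rose, 4 rose and 2 fell, and 2 rose (adjusted p = 0.33, 0.27 and 0.558).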

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

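The tests of a larger response of all genes in TMD8, of compressed ratios on the MLN120b array at 24 h and of the normalization within arrays were chosen only after the result was seen. NF-kB targets under 15e differed between the lines by a test of the difference itself (median difference -0.49, adjusted p = 0.628 with an estimated correlation), and so did their members NFKBIA (-0.98), TNFAIP3 (-0.96), BCL2A1 (-0.44), IRF4 (-1.37), CD44 (-1.05), IL6 (-2.03) and IL10 (-2.02). The 39 targets well above background in DMSO on all 8 arrays differed by a median of -0.48. The 95% bootstrap over genes, as if independent, gave -0.75 to -0.20. The median argues against targets near background in HBL1. The SD of mean log2 ratios over genes in TMD8 was 0.944 times that in HBL1, which argues against a larger response of all genes. Slide or scan stays open, since 0 slides carried both lines and they cannot be told apart, and so does the untested difference between the lines themselves.

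The MLN120b array at 24 h was flagged by 2 values far from its group, the MHC class II median (0.57) and TNFAIP3 (-0.25). Its spike-in log2 ratios spanned 6.22 between bright probes (others 5.72 to 6.03), which argues against compressed ratios of bright genes only. The slope of its log2 ratios on the mean of 15e in HBL1 was 0.194 over 1210 genes, which argues against an array of 15e in place of MLN120b. The NF-kB targets lay at -0.14 against genes of like brightness (95% bootstrap over genes -0.26 to -0.04, others -0.71, -0.67 and -0.51). Loess had already levelled such genes, so a curved dye response stays open. So do the time itself and a difference in that culture, since 24 h had no other MLN120b array, and no biological explanation was tested.

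Spike-in controls, which no comparison uses, lay above the median gene on the TMD8 arrays by 0.87, 0.65, 1.21 and 2.09 at 12, 24, 36 and 48 h, which flagged them as a signal outside the main measurement. The gap to 15e in HBL1 was 1.37 (2-sided permutation p = 0.0286, the smallest possible, with times mixed). Over 3 normalizations the smallest gap was 1.22, which argues against the normalization, and the gap over the 5 brightest probes exceeded that over the 5 dimmest by 0.21, which argues against dim signals. Unequal amounts of RNA or of spike-in RNA stay open (2.09 at 48 h), since the amounts were not given. A biological explanation, less RNA per treated cell, was not tested.

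The number of genes that differed between the lines under 15e was flagged by the test of the difference itself (3772). In the same way lists differed by camera, none of them with an estimated correlation (adjusted p = 0.601 to 0.893), for interferon response (-0.18), FOXO targets (-0.24), replication histones (0.51), ATF4 targets (-0.33), ribosomal proteins (-0.23), germinal centre (-0.47) and MHC class II (-0.49). Genes with a negative difference were CTSF (-3.33), STRA8 (-3.29), EGR2 (-2.62), ID2 (-2.61), ARHGEF10 (-2.60), CHST12 (-2.44) and PIK3IP1 (-0.78). Genes with a positive difference were TNFRSF21 (3.38), UCHL1 (2.51), RGS1 (2.36), HEPACAM2 (2.21), OSR2 (2.21), RNU12 (2.14) and CCND2 (1.02). For CTSF, STRA8 and UCHL1 (in TMD8) and for HEPACAM2 and OSR2 (in HBL1) at least 1 channel of the line named was not above background, so these sizes are not differences between 2 measured changes.

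Single arrays lay far from the other 3 of their group for 11 of 135 groups of 4, where chance flags about 1 in 20. Besides the 2 of the MLN120b array at 24 h, these were on the HBL1 array of 15e at 36 h NFKBIA (-1.24), CCL3 (-1.56), CCL4 (-2.24, with the inhibitor channel not well above background, so not a measured size) and IKBKB (-0.14). At 48 h in HBL1 it was the median of plasma cell genes (-0.13). In TMD8 they were the medians of proliferation (-0.35) and glycolysis (-0.16) and CD44 (0.044) at 12 h, and the median of FOXO targets at 48 h (0.30).

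Other splits of the arrays gave fewer calls. For the difference between the lines, 1 of 35 splits, the real one with 3772 genes, reached that count, and the highest other count was 22. These splits mix the times, and the 8 that keep every time on both sides (highest other count 0) are too few to decide. For the group means (1 of 8 splits each) and the difference between inhibitors (1 of 10), the splits were too few to decide.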

How the results depend on the processing

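The test without the MLN120b array at 24 h was chosen only after the data were seen. It was compared for 15e and for the genes lowered by MLN120b, where 9 main results and 246 others stayed the same, 4 were weaker and 3 stronger (IL10 and PIK3CD in HBL1 and PIK3CD between lines). MLN120b (3754 genes against 2995) and the difference between inhibitors (643 against 1032), which use this array, lost calls of genes and lists without it. Among the named genes, 942 results under other settings kept their direction and side of the threshold, 155 were weaker, 23 stronger and 53 reversed, and without 1 array these numbers were 1400, 252, 14 and 11. For list calls they were 246, 174 weaker and 10 reversed, and without 1 array 414, 37 and 4. For each value below, the cause was not tested.

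The counts of genes called for MLN120b (2995) were 5291 with the scanner's ratios, 15988 with median centring, 1983 with the deposited table, 4610 with no filter, 1158 with the strict filter (fewer genes tested), 3 with the MLN120b arrays alone and 657 with a minimum mean of 0.5. That minimum left 5028 for 15e in HBL1 and 4398 in TMD8. The slide as a block (15972, 14963 and 8765 for the means, 12419 between lines) decides nothing. With 1 slide per 15e group, its correlation (-0.255) rests on MLN120b. Between lines the count was 2327 with the strict filter and 1632 with median centring. Between inhibitors it was 472 with the scanner's ratios, 490 with median centring, 187 with the deposited table and 4229 with all 4 arrays of each. Trends of 15e in HBL1 numbered 145 with the scanner's ratios, 2 with median centring and 245 with the deposited table. Those in TMD8 numbered 1165 without background correction, 183 at an offset of 10, 228 with median centring and 123 on linear hours. Trends of MLN120b (0) numbered 1 with the scanner's ratios, an offset of 10 or the deposited table and 4 on linear hours. Calls shared by 15e and MLN120b numbered 3000 in HBL1 and 2249 for TMD8 with the scanner's ratios, and 886 and 840 with the strict filter.

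With median centring the share of higher calls moved, its shift kept as in the counts above. It was 82.5% for 15e in HBL1 (52.4% with loess), 87.6% in TMD8 (52.4%) and 39.3% between lines (54.6%). For 15e trends it was 100% of the few in HBL1 (22.9%) and 3.07% in TMD8 (38.7%). In TMD8 that share of trends was 23.0% with the scanner's ratios, 23.9% with the deposited table and 26.8% at an offset of 10. With the deposited table it was 59.2% for MLN120b (71.1%) and 47.6% between inhibitors (33.9%).

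The time point as a block left 622 genes between inhibitors (1032 without it).

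With an estimated correlation, list calls numbered 0 for means and 0 for trends. Fry kept 31 of 60 list calls on means and differences and 1 of 26 on trends. For the genes lowered by MLN120b, the adjusted p with an estimated correlation was 0.161 in HBL1, 0.161 in TMD8 and 0.651 for the trend in HBL1, where fry gave 0.566.

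Median centring kept 158 of 251 results of named genes. It reversed, for 15e in HBL1, NFKBIA (0.23), TNFAIP3 (0.27), IRF4 (0.33), MYC (0.19), IL10 (0.068), KLF2 (0.30), IKBKB (0.26) and NDUFB8 (0.19), none of them (0) once the shift of all genes was taken off. In TMD8 it reversed BCL2A1 (0.31), CD44 (0.66), IKBKB (0.21) and PIK3CD (0.31), all 4 also relative to the shift. For MLN120b it reversed NFKBIA (0.11), BCL2A1 (1.16), IRF4 (0.40), MYC (1.04), CD44 (1.21), IL6 (0.19), IL10 (0.84), CCND2 (0.99), PIK3IP1 (0.25), KLF2 (1.19), IKBKB (0.78), PIK3CD (0.72), BATF (0.78), STAT3 (0.20), IFIH1 (0.15), MCM7 (1.11), SLC1A5 (0.071), MTHFD2 (0.93), ENO1 (1.05) and BIRC3 (0.40), of which 12 also relative to the shift. Between lines it reversed IKBKB (-0.044), and between inhibitors BCL2A1 (-0.29), IRF4 (-0.16), PIK3CA (-0.17) and RPS20 (-0.091). Lists whose direction in camera's test, which need not be that of their median, it reversed were, with adjusted p, oxidative phosphorylation in HBL1 under 15e (0.376), ribosomal proteins (0.00223) and MHC class II (0.577) between inhibitors, and under MLN120b interferon (0.996), MYC (0.00142), proliferation (0.143), ATF4 (0.673), glycolysis (0.553), BCL2 family (0.0632) and heat shock (0.0352). The mean over probes reversed IKBKB (0.10 in HBL1, 0.025 in TMD8), and the scanner's ratios and the deposited table PIK3IP1 (0.24) and PIK3CA (-0.015) under MLN120b. The mean over probes also reversed IKBKB between lines (-0.077) and inhibitors (0.083) and KLF2 between inhibitors (0.0080). Between lines, the scanner's ratios and the deposited table reversed PRDM1 (-0.089), PIK3CA (0.088) and CCL4 (0.28 and 2.14), which was near background in HBL1, and the deposited table CCL3 (0.34).

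Without 1 array, counts ranged from 119 to 3754 for MLN120b, 2385 to 4286 between lines, 0 to 1200 between inhibitors, and 0 to 272, 2 to 690 and 0 to 2 for the trends of 15e in HBL1, 15e in TMD8 and MLN120b. Under MLN120b, BCL6 ranged from -0.062 to 0.43, IL6 from -0.10 to 0.029, PIK3CA from -0.026 to 0.032 and PIK3IP1 from -0.14 to 0.079. Differences ranged from -0.27 to 0.080 for PIK3CA between lines, and between inhibitors from -0.23 to 0.0076 for MYC and -0.39 to 0.16 for KLF2. The slopes of MED18 in HBL1 ranged from -0.013 to 1.48, and in TMD8 those of PHGDH from -1.64 to 0.20 and SNAI2 from -0.028 to 1.82. Adjusted p of trends ranged from 2.32e-14 to 0.0758 for ATF4 targets and amino acid metabolism and from 0.00577 to 0.445 for the genes lowered by MLN120b, both in TMD8. Under MLN120b they ranged from 1.40e-12 to 0.389 for MYC and ribosome biogenesis, 6.50e-10 to 0.290 for cell proliferation and 1.18e-07 to 0.389 for glycolysis and hypoxia.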

Other observations

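H2B histone genes rose with MLN120b in HBL1, a feature singled out after its values were seen. Of 16 H2BC genes tested, 15 rose under MLN120b. The medians of the 6 H2B genes among its highest means were 0.58, 1.17, 1.37 and 2.06 at 6, 12, 24 and 48 h. With 15e in HBL1 they were 0.52, 0.80, 0.42 and 0.94 at 12, 24, 36 and 48 h, and in TMD8 -0.09, -0.05, 0.04 and 0.03. These genes are near-identical copies, so they count as about 1 signal.

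Replication histones as a list were not called under 15e in either line. In HBL1, 6 of 28 rose, 14 fell and 8 were not called, and 6 rose and 15 fell when adjusted over the list alone (median -0.36, adjusted p = 0.096). In TMD8, 7 rose, 1 fell and 20 were not called, and 6 rose and 1 fell when adjusted over the list alone (median 0.18, adjusted p = 0.175).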
